A study of Mus musculus with 15 samples.

How the data were processed

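RNA sequencing libraries were made from 5 populations sorted by flow cytometry from fresh bone marrow of healthy mice, 3 libraries per population, with the Universal Plus mRNA-Seq kit (NuGEN) per the labels. The authors deposited one table of log2 CPM values (reads scaled to library size) for 14801 genes by Entrez identifier. Per the submitters' processing notes, FastQC 0.11.7, featureCounts 1.22.2 and edgeR 1.30.5 were used with the GRCm38 (mm10) build; the aligner, the strand setting of the counting and the gene annotation are not given in the sources used here. Each deposited log2 value equals the log2 of a whole number plus 0.5 times a step that is constant within a library. This holds for 100% of values in all 15 libraries (tolerance 0.001 reads), so reads per gene and library could be recovered. The recovered totals cover the genes of the table, which is not shown to be the whole of each library.

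Recovered totals were 953362, 1174210 and 1444403 reads for CMP replicates 1 to 3, 1284327, 931720 and 810794 for CD115plusGMP, and 887982, 1283806 and 1401958 for Neutrophil. They were 12977429, 11318009 and 68171606 for PreNeut_Neutrophil and 7493694, 9973168 and 13397126 for ProNeut_Neutrophil. The deposited values imply a library size of 0.254 to 0.908 times this total in the first 3 groups and 1.93 to 2.24 times it in the last 2. The column names of the first 3 groups end in a read-file suffix and those of the last 2 do not. From 3672 to 8266 genes had 0 reads in a library of the former, and 1681 to 2457 in a library of the latter.

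Groups were taken from the sample labels, and all 15 libraries were used. Before values were averaged, replicates were compared over genes by a chi-square test of the recovered reads; chi-square per degree of freedom was 2.32 to 23.8, so every pair of libraries differed by more than sampling noise. Replicate numbers were not used to pair libraries across groups.

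Choices of comparisons, tests, gene lists and the rule for naming genes were made before the data were examined. Genes with a log2 CPM above 0 in at least 3 of the 15 libraries were tested. Group means were fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend), with all 15 libraries sharing one estimate of the spread per gene. P-values were 2-sided and adjusted by Benjamini-Hochberg over the genes tested in each comparison. A gene was called when its adjusted p was under 0.05 and its absolute log2 difference at least 1. All 10 pairs of groups were compared, 6 of them as main comparisons with named genes, and a moderated F-test covered all 5 groups. The plan held a count-based test for the case that the table held counts; it holds log2 values, so the log2 test was used.

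The 31 gene lists fixed beforehand were azurophilic, specific and gelatinase granules, mature neutrophil, NADPH oxidase, granulocyte transcription factor, monocyte and macrophage, dendritic cell and MHC class II, plasmacytoid dendritic cell, stem and multipotent progenitor, erythroid, megakaryocyte and platelet, eosinophil, basophil and mast cell, B lymphoid, T and NK cell, marrow stroma and endothelium, DNA replication, mitosis, ribosomal protein, oxidative phosphorylation, glycolysis, ER protein folding, interferon-stimulated, adhesion and chemotaxis receptor, pattern recognition, tumour-associated myeloid factor, immediate early and stress, mitochondrially encoded, sort and surface, and sex-linked. The last 2 served as checks of the labels and were not tested. The other 29 were tested with limma camera (preset correlation 0.01), with adjusted p over lists within a comparison; an estimated correlation and fry were alternatives. Members called were counted over all genes tested and again adjusted over the list alone.

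Named genes are, per main comparison, the 8 with the largest increase and the 8 with the largest decrease among called genes. Their groups of libraries had to be without overlap, and the higher group had to have a mean log2 CPM of at least 5. Predicted-gene symbols and bare identifiers were passed over. Up to 4 members of each list described were added, those with the largest absolute difference, called ones first. Genes of the sort and surface and the sex-linked lists could be named in any comparison. Some genes that this rule picks are not reported here.

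A log2 difference against a group with 0 reads depends on depth and on the 0.5 added, so such genes are given as at least N-fold, from read totals scaled by library size and a floor of 3 reads over the group. With 1 to 3 reads, the ratio of scaled reads is given with its 95% counting interval. Coordinates (GRCm38, first base numbered 1) and strands came from GENCODE M21. To it 14054 genes could be matched by Entrez identifier or, where that failed, by a unique symbol. Of these, 4285 share at least 50 bases of exon with a gene on the opposite strand, the measure used for named genes; shares of called genes, and the alternative without such genes, count any overlap of gene bodies. None of the 503 identifiers without a symbol could be matched, and they were kept in the tests.

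The procedure was tested on simulated data with the observed depths, 200 changed genes and 13941 unchanged ones. The replicate spread was set to the same value for every gene and group, not taken from the data. Within a library set, 11 to 194 unchanged genes were called: 111 for CD115plusGMP against CMP, 11 for ProNeut_Neutrophil against PreNeut_Neutrophil, 194 for Neutrophil against CMP and 100 for Neutrophil against CD115plusGMP. Between sets 1881 to 3996 were called: 1881 and 2706 for PreNeut_Neutrophil against CMP and CD115plusGMP, and 1917 and 2759 for ProNeut_Neutrophil against these. For Neutrophil against PreNeut_Neutrophil and ProNeut_Neutrophil they were 3996 and 3983. With 5 CPM added before the log, false calls were 0 to 22 in any comparison. Without this addition, 86.4%, 86.4%, 78.8% and 92.4% of 8-fold changes were recovered within sets, in the same order, and 86.4% to 100% between sets. With 5 CPM added, 80.3%, 68.2%, 75.8% and 89.4% were recovered within sets, and 69.7% to 95.5% between sets. Counts between sets therefore include genes whose difference comes from depth.

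Alternatives were no filter, a filter at a log2 CPM of 2, log2(CPM + 1), log2(CPM + 5), quantile normalization, median centring, the 2 groups alone, eBayes without trend or robust, array weights, replicate number as a block, no fold minimum, and leaving out each library in turn. Added after the data were seen were voom weights, plain library totals, reads thinned to equal depth (810794 per library over all identifiers, so that genes with a symbol keep fewer reads in the first set), at least 10 reads in 3 libraries, genes without opposite-strand overlap, and the library set of the groups alone. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.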

Results

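RNA was sequenced from 5 populations sorted by flow cytometry from fresh bone marrow of healthy mice, with 3 libraries per population and 15 in all. The labels name them CMP (common myeloid progenitors), CD115plusGMP (granulocyte-monocyte progenitors carrying CD115, the receptor for colony-stimulating factor 1), PreNeut_Neutrophil, ProNeut_Neutrophil and Neutrophil. The names PreNeut_Neutrophil and ProNeut_Neutrophil are shortened to PreNeut and ProNeut here. Values are log2 CPM, reads scaled to library size on the log2 scale, for 14801 genes, of which 14161 were tested. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

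The libraries fell into 2 sets that follow the groups, called the first and the second set here. The first set holds the 9 CMP, CD115plusGMP and Neutrophil libraries, with 810794 to 1444403 reads each over the genes of the table. The second set holds the 6 PreNeut and ProNeut libraries, with 7493694 to 68171606 reads each; PreNeut replicate 3 is the deepest. In the first set 55.6% to 69.5% of reads lay on 503 identifiers without a gene symbol, against 0.102% to 0.146% in the second. ND6, the one mitochondrial protein gene on the strand opposite to the other 12, took 69.1% to 93.3% of the reads of the 13 mitochondrial genes in the first set and 0.154% to 0.230% in the second. Tsix, the antisense partner of Xist, had 9651 reads in the first set against 535 for Xist, and 30 against 43 in the second. In each of the 9 first-set libraries, genes that overlap on opposite strands followed the partner's second-set values more than their own (rank correlation higher by 0.0696 to 0.269). Every first-set value, also in comparisons within that set and for genes with no annotated partner, may therefore count mainly reads from the strand opposite to the gene, and is a value for the gene's locus. A gene with 0 reads has a log2 CPM of -1.31 to 0.63 in the first set and of -8.14 to -4.90 in the second. Each comparison of a group of the first set with a group of the second therefore compares the sets as well, and set and group cannot be told apart there.

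Across genes, the median Pearson r between libraries of one group was 0.901 (0.820 to 0.974). It was 0.718 between groups of one set and 0.192 (0.102 to 0.350) between sets. The 0.718 pools unlike pairs. PreNeut with ProNeut libraries had a median r of 0.953, against 0.943 within PreNeut and 0.969 within ProNeut. Pairs of first-set groups had medians of 0.520 to 0.788. Genes are not independent replicates. Neutrophil libraries had a median r of 0.520 with CMP libraries and of 0.231 with ProNeut libraries. The first principal component, with 73.1% of the variance, separated the sets, and the second, with 12.2%, separated the groups of the first set. PreNeut replicate 3 stood apart from its group, at 393 on the first component against 288 and 289, and at -93.2 on the third against -0.078 and -4.37. In the limma F-test over the 5 groups, 12055 of 14161 genes (85.1%) passed an adjusted p of 0.05.

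**Figure D1:**
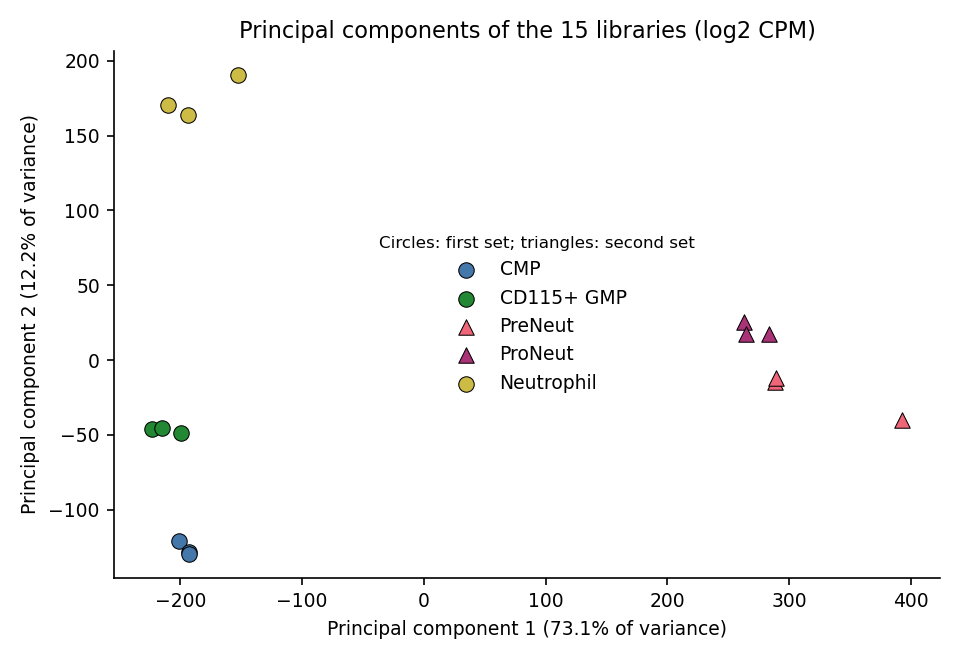
First and second principal components of log2 CPM for the 15 libraries, 3 points per group, with the share of variance on each axis. Circles are libraries of the first set and triangles those of the second; the sets part along the first component, which holds 73.1% of the variance.

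The comparison of CD115plusGMP with CMP asks what distinguishes the progenitor sorted on CD115 from the less committed one. Genes of azurophilic granules, the first granules made in granulocyte development, rose in CD115plusGMP. Elane, which encodes neutrophil elastase, had 101 reads in CD115plusGMP and 0 in CMP, at least 58.4-fold higher. Mpo (myeloperoxidase) was higher by 6.41 ± 0.84 log2 units (SE, n = 3; adjusted p = 8e-05). Prtn3 (proteinase 3) had 141 reads against 2, a ratio of 122 (95% counting interval 33.2 to 1020); its fitted difference of 6.41 was 7.32 without CMP replicate 1. Ctsc, whose product activates the granule proteases, had 65 reads against 0, at least 37.6-fold higher. Such intervals and floors cover counting error only and hold for the deposited library sizes.

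Of 10 azurophilic granule genes tested, 7 rose and none fell, with a median of 5.10 (4.56 from read ratios with zero-read genes at their bound; camera adjusted p = 9.6e-08; adjusted p = 0.0087 with an estimated correlation). Monocyte and macrophage genes rose in 14 of 20 (16 adjusted over the list alone; adjusted p = 0.0087 with an estimated correlation). Among them, the coagulation factor subunit F13a1 was higher by 6.63 ± 1.10 (SE, n = 3; limma adjusted p = 0.00059; 5.74 without CMP replicate 2, 7.74 without CMP replicate 1), and the fibronectin gene Fn1 had a read ratio of 61.5 (16.4 to 518; fitted difference 5.41, and 6.18 without CMP replicate 2). All 6 NADPH oxidase genes rose; Cybb, the catalytic subunit, was higher by 5.69 ± 0.62 (5.03 without CMP replicate 3, 6.73 without CMP replicate 2). Of 9 granulocyte transcription factor genes, 5 rose (6 over the list alone), with Cebpb higher by 3.37 ± 0.38. Cebpa had 69 reads against 3, a ratio of 39.9 (13.1 to 198), and Cebpe 12 against 1, a ratio of 20.8 (3.08 to 889). Of the surface protein genes commonly used in sorting, Csf1r, which encodes CD115 itself, had 27 reads against 2, a ratio of 23.4 (5.88 to 203; fitted difference 4.10, and 4.86 without CMP replicate 2). The mean of Csf1r was 5.16 ± 1.28 (SD, n = 3) in Neutrophil against 3.81 ± 0.64 in CD115plusGMP, the group named for it. This difference did not pass (1.35 ± 0.74, SE; adjusted p = 0.19) and the libraries overlapped, so the order of these 2 groups is open. Fcgr3, a CD16/32 gene, had 35 against 1 (ratio 60.7, 10.2 to 2460; fitted difference 4.18, and 3.57, 5.26 and 4.84 without CD115plusGMP replicate 1, CD115plusGMP replicate 2 and CMP replicate 1), and Ly6c2 39 against 3 (ratio 22.5, 7.16 to 114).

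Erythroid genes fell in CD115plusGMP: 10 of 13 were lower (median -4.39, -3.87 at the bound; adjusted p = 0.0059 with an estimated correlation). Ermap, an erythroblast membrane protein gene, had 0 reads against 310 in CMP and was at least 59.6-fold lower. The carbonic anhydrase genes Car1, with 0 against 263, and Car2, with 3 against 648, were lower at least 50.6-fold and by a ratio of 125 (42.4 to 606). Of 17 stem and multipotent progenitor genes, 4 fell and 1 rose, which did not pass as a list (camera adjusted p = 0.095). Tal1, a transcription factor of blood stem and erythroid cells, had 1 read against 107, a ratio of 61.7 (10.8 to 2460). Angpt1, an angiopoietin gene, had 0 against 37 and was at least 7.11-fold lower.

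The other genes with the largest differences at a mean log2 CPM of at least 5 were less familiar ones. Higher in CD115plusGMP were BB031773 (8.25 ± 0.80), Tmem198b (7.28 ± 0.54) and the netrin receptor gene Unc5a (6.48 ± 0.86). Prune2 and Ptgir, the prostacyclin receptor gene, had 0 reads in CMP and were at least 80.3-fold and 49.7-fold higher. Lower were Mfsd9 (-6.75 ± 0.91) and Eps8l3 (-6.60 ± 0.73). Zfp341 had 1 read against 465, a ratio of 268 (47.9 to 10600; fitted difference -6.92, and -7.53 without CD115plusGMP replicate 2). Hcn3, Necab1 and AA986860 had 0 reads in CD115plusGMP and were at least 75.9-fold, 59.6-fold and 52.5-fold lower. When 1 CMP library was left out, BB031773 was at 7.38 (replicate 2) and 8.93 (replicate 1) and Unc5a at 5.63 and 7.50; Mfsd9 was at -6.04 without CD115plusGMP replicate 2 and -7.63 without replicate 3. All of these genes but Prune2, Ptgir and Unc5a overlap exons of an annotated gene on the opposite strand. So do Mpo, Prtn3, F13a1, Fn1, Csf1r, Cebpa, Cebpb and Angpt1, and reads of the partner gene were not separated from theirs; the strand limit of the first set holds for all genes here.

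In total 1790 genes passed in CD115plusGMP against CMP (limma, Benjamini-Hochberg adjusted p under 0.05 and at least 1 log2 unit), 1144 higher and 646 lower. The libraries of the groups did not overlap for 39.3% of genes. Chance gives 10% only for libraries alike in depth and scaling. The value of 0 reads was higher in every CD115plusGMP library than in every CMP library. The 686 tested genes with 0 reads in both groups are therefore non-overlapping by construction. Of 29 lists tested with camera, 14 passed and 6 did with an estimated correlation. Lists lost then include DNA replication, with 5 of 22 lower (adjusted p = 0.094 with an estimated correlation), and mitosis, with 2 of 21 lower (adjusted p = 0.26). They also include specific granules, with 3 of 12 higher (adjusted p = 0.22). Without CMP replicate 3 or CD115plusGMP replicate 2 the gelatinase granule list, with 2 of 8 higher, did not pass (adjusted p = 0.0825 and 0.0557; adjusted p = 0.22 with an estimated correlation). Nor did ER protein folding, with 4 of 15 higher, without CD115plusGMP replicate 1 (0.0781; adjusted p = 0.26 with an estimated correlation). Depth and scaling alone give the 686 tested genes with 0 reads in both groups a difference of 0.80, and 0 of them were called. The medians of the specific and gelatinase granule lists were also 0.80, and only 7 of 12 and 2 of 8 members had enough reads for a ratio. The passes of these 2 lists may therefore rest in part on genes without reads. The split into higher and lower followed the scaling: 1493 and 1302 with quantile normalization, 1291 and 302 with median centring, 696 and 1383 with plain library totals. These scalings moved the median of all genes by -0.31, 0.35 and -0.56.

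ProNeut and PreNeut are the sorted neutrophil progenitor subsets, and both belong to the second set. Genes of late granules were higher in ProNeut and genes of early granules lower. Mmp8, the neutrophil collagenase gene, rose by 7.20 ± 0.61 log2 units (SE, n = 3; limma adjusted p = 1.5e-05), from 2.44 ± 0.34 (SD) in PreNeut to 9.64 ± 0.21. Mmp9, the gelatinase gene, rose by 4.39 ± 0.40 (adjusted p = 3e-05) and Retnlg, a resistin-like gene of mature neutrophils, by 4.82 ± 0.48 (adjusted p = 5.1e-05). Elane was at 3.40 ± 0.89 in ProNeut against 8.39 ± 0.18 (SE of the difference 0.62; adjusted p = 0.00038). Mpo (-4.46 ± 0.84; -3.71 without ProNeut replicate 3, -5.22 without ProNeut replicate 2) and Prtn3 (-4.30 ± 0.67) were also lower. In GRCm38, Elane (Entrez 50701) lies on chromosome 10 at 79886247 to 79888215 and Mmp8 (Entrez 17394) on chromosome 9 at 7558456 to 7568485.

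Of 10 azurophilic granule genes, 6 fell and none rose (7 adjusted over the list alone; median -2.06, -2.02 at the bound; camera adjusted p = 2e-14; adjusted p = 0.0012 with an estimated correlation). They include Ctsg, the cathepsin G gene (-3.48 ± 0.85), the membrane protein gene Ms4a3 (-2.10 ± 0.51) and Srgn, the granule proteoglycan serglycin (-2.01 ± 0.33). Of 8 gelatinase granule genes, 5 rose (6 over the list alone; median 2.72, 2.58 at the bound; adjusted p = 0.0034 with an estimated correlation), led by the formyl peptide receptor gene Fpr1 at 4.78 ± 0.77 (4.18 without PreNeut replicate 3). Of 20 mature neutrophil genes, 6 rose (10 over the list alone; adjusted p = 0.0034 with an estimated correlation). Mmp8 was the 1 specific granule gene of 12 that passed; the list passed camera (adjusted p = 0.034) but not with an estimated correlation (adjusted p = 0.52). It also did not pass without PreNeut replicate 1, PreNeut replicate 2 or ProNeut replicate 3 (adjusted p = 0.105, 0.177 and 0.091). Ms4a3 lost its call without any 1 of the 6 libraries (adjusted p = 0.0797 to 0.144). Ctsg lost it without any but ProNeut replicate 2 (0.0841 to 0.187); its value was -2.56 without ProNeut replicate 3 and -4.35 without ProNeut replicate 2, and -3.54 to -3.45 otherwise.

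DNA replication genes were lower in ProNeut, with 6 of 22 called (13 over the list alone; median -1.53, -1.54 at the bound; adjusted p = 0.0031 with an estimated correlation). Pcna, the replication clamp gene, was lower at -2.03 ± 0.41 and the cyclin gene Ccne2 at -2.02 ± 0.38. The call of Pcna was lost without PreNeut replicate 3 (adjusted p = 0.0654) or ProNeut replicate 1 (0.0772). None of 21 mitosis genes passed in limma, and 0 were at an unadjusted p under 0.05 (median 0.14; camera adjusted p = 0.8). Ribosomal protein genes were lower as a list (median -0.66; adjusted p = 0.0049 with an estimated correlation) with none of 80 called (3 lower at an unadjusted p under 0.05), as were mitochondrially encoded genes (median -1.03; adjusted p = 0.0034 with an estimated correlation) with none of 13 called (7 lower at an unadjusted p under 0.05).

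Erythroid genes were higher in ProNeut, with 7 of 13 called (12 over the list alone; median 3.45, 2.91 at the bound; adjusted p = 0.0012 with an estimated correlation). Car1 rose by 4.51 ± 0.47, with 842 reads against 137. Klf1, the erythroid transcription factor gene, was higher by 5.59 ± 1.29, with 164 reads against 21. Its call was lost without any 1 library but PreNeut replicate 1 (adjusted p = 0.0578 to 0.103), and its value was 3.62 without PreNeut replicate 3 and 7.49 without PreNeut replicate 1. Basophil and mast cell genes were lower, with 4 of 5 called (median -3.87, -3.60 at the bound; adjusted p = 0.0034 with an estimated correlation). The serine protease genes Prss34 and Mcpt8, of basophils, were lower at -4.24 ± 0.61 and -4.22 ± 0.53.

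Of 10 tumour-associated myeloid factor genes, 3 rose (4 over the list alone; adjusted p = 0.036 with an estimated correlation). The chemokine-like gene Prok2 had 157 reads in ProNeut and 0 in PreNeut, at least 164-fold higher. Its fitted difference of 7.83 was 7.03 without PreNeut replicate 3. PreNeut bounds and ratios, here and below, rest mainly on that library, the deepest of its group. The arginase gene Arg2 rose by 6.91 ± 0.51 and the kinase gene Bmx by 3.18 ± 0.45. Interferon-stimulated genes rose in 2 of 14 (6 higher and 1 lower over the list alone; adjusted p = 0.036 with an estimated correlation). Oas3 was higher by 2.45 ± 0.52 and Usp18 had 46 reads against 2, a ratio of 72.1 (18.9 to 613). Of 11 pattern recognition genes, Nlrp3 (3.38 ± 0.67) and Tlr13 (2.85 ± 0.62) were higher (adjusted p = 0.2 with an estimated correlation). This list did not pass without PreNeut replicate 1, PreNeut replicate 2 or ProNeut replicate 3 (adjusted p = 0.139, 0.0976 and 0.0746). The plasmacytoid dendritic cell list passed (adjusted p = 0.021 with an estimated correlation) with Siglech alone called of 8 (3.51 ± 0.82; 4 over the list alone). Of 4 T and NK cell genes, Cd3d was higher (3.48 ± 0.79) and Nkg7 lower (-3.34 ± 0.71), and the list did not pass (camera adjusted p = 0.36).

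Several of these calls were lost with 1 library fewer, most at a similar value. Oas3 lost its call without PreNeut replicate 3, ProNeut replicate 1 or ProNeut replicate 2 (adjusted p = 0.0785, 0.103 and 0.0643), at 2.24, 2.19 and 2.50. Usp18 lost it without ProNeut replicate 1 or 2 (0.0526 and 0.0752), at 4.94 and 4.49 (4.95 with all), and was at 5.59, 5.64 and 3.61 without PreNeut replicate 1, 2 and 3. Nlrp3 lost it without PreNeut replicate 3 or ProNeut replicate 1 (0.0506 and 0.0512), at 3.09 and 3.34. Tlr13 and Cd3d lost it without PreNeut replicate 3 or any 1 ProNeut library (0.0643 to 0.0847 and 0.0679 to 0.098). Tlr13 was then at 2.75 to 2.96; Cd3d was at 2.43 without PreNeut replicate 3 and 4.08 without PreNeut replicate 1. Siglech lost it without any but PreNeut replicate 1 (0.0585 to 0.12), and Nkg7 without PreNeut replicate 1, ProNeut replicate 2 or ProNeut replicate 3 (0.0533, 0.0533 and 0.0941), at -3.50 to -2.95. Siglech was at 2.82 without PreNeut replicate 2 and 4.72 without PreNeut replicate 1.

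In the remaining lists no member passed in limma, with 0 to 4 per list at an unadjusted p under 0.05. ER protein folding was lower as a list (median -0.39; camera adjusted p = 0.006; adjusted p = 0.26 with an estimated correlation). NADPH oxidase (median 0.21), granulocyte transcription factor (0.04), monocyte and macrophage (-0.31) and stem and multipotent progenitor genes (0.51) did not pass camera, with adjusted p = 0.63, 0.54, 0.32 and 0.37. Nor did dendritic cell and MHC class II genes (0.18; adjusted p = 0.41), megakaryocyte and platelet genes (0.46; 0.91), eosinophil genes (-0.72; 0.2), B lymphoid genes (0.45; 0.91) or marrow stroma and endothelium genes (1.02; 0.41). Oxidative phosphorylation (-0.09; 0.16), glycolysis (0.05; 0.97), adhesion and chemotaxis receptor (0.35; 0.19) and immediate early and stress genes (0.66; 0.23) did not pass either. Among surface genes commonly used in sorting, Ly6g was at 7.83 ± 0.15 in ProNeut and 5.17 ± 0.08 in PreNeut (2.66 ± 0.80; adjusted p = 0.12). The chemokine receptor gene Cxcr2 was at 6.97 ± 0.17 and 5.31 ± 0.26 (1.66 ± 0.50; adjusted p = 0.12), and Kit did not pass either (-0.44 ± 0.50; adjusted p = 0.97). These SEs pool the spread of all 15 libraries, while the SDs of Ly6g and Cxcr2 within the 2 subsets were smaller. Their missing calls therefore do not show that Ly6g and Cxcr2 are equal in ProNeut and PreNeut.

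Further genes among the largest increases in ProNeut were the calcium channel gene Trpm2 (4.71 ± 0.61), the receptor kinase gene Acvrl1 (3.97 ± 0.63), the thrombospondin gene Thbs1 (3.92 ± 0.52) and the kinase gene Map4k4 (3.58 ± 0.57). Of the genes named in this comparison, Mpo, Prtn3, Ccne2, Arg2, Usp18, Acvrl1 and Thbs1 overlap exons of an opposite-strand gene. In total 320 genes passed, 261 higher and 59 lower. The libraries did not overlap for 36.0% of genes, where chance gives 10% only for libraries alike in depth and scaling. The count was 198 without ProNeut replicate 1 and 195 without ProNeut replicate 2. It depended on the model of the spread: 903 genes passed with the 6 libraries of the second set alone, 1433 with array weights and 1363 with voom weights. With quantile normalization 76 genes were higher and 45 lower. On simulated data 1.49% of 2-fold changes were recovered. The simulation set the same replicate spread for every gene, and a 2-fold change lies at the cut of 1 log2 unit. Changes of that size can therefore go uncalled here, at a rate that the simulation does not give.

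**Figure D2:**
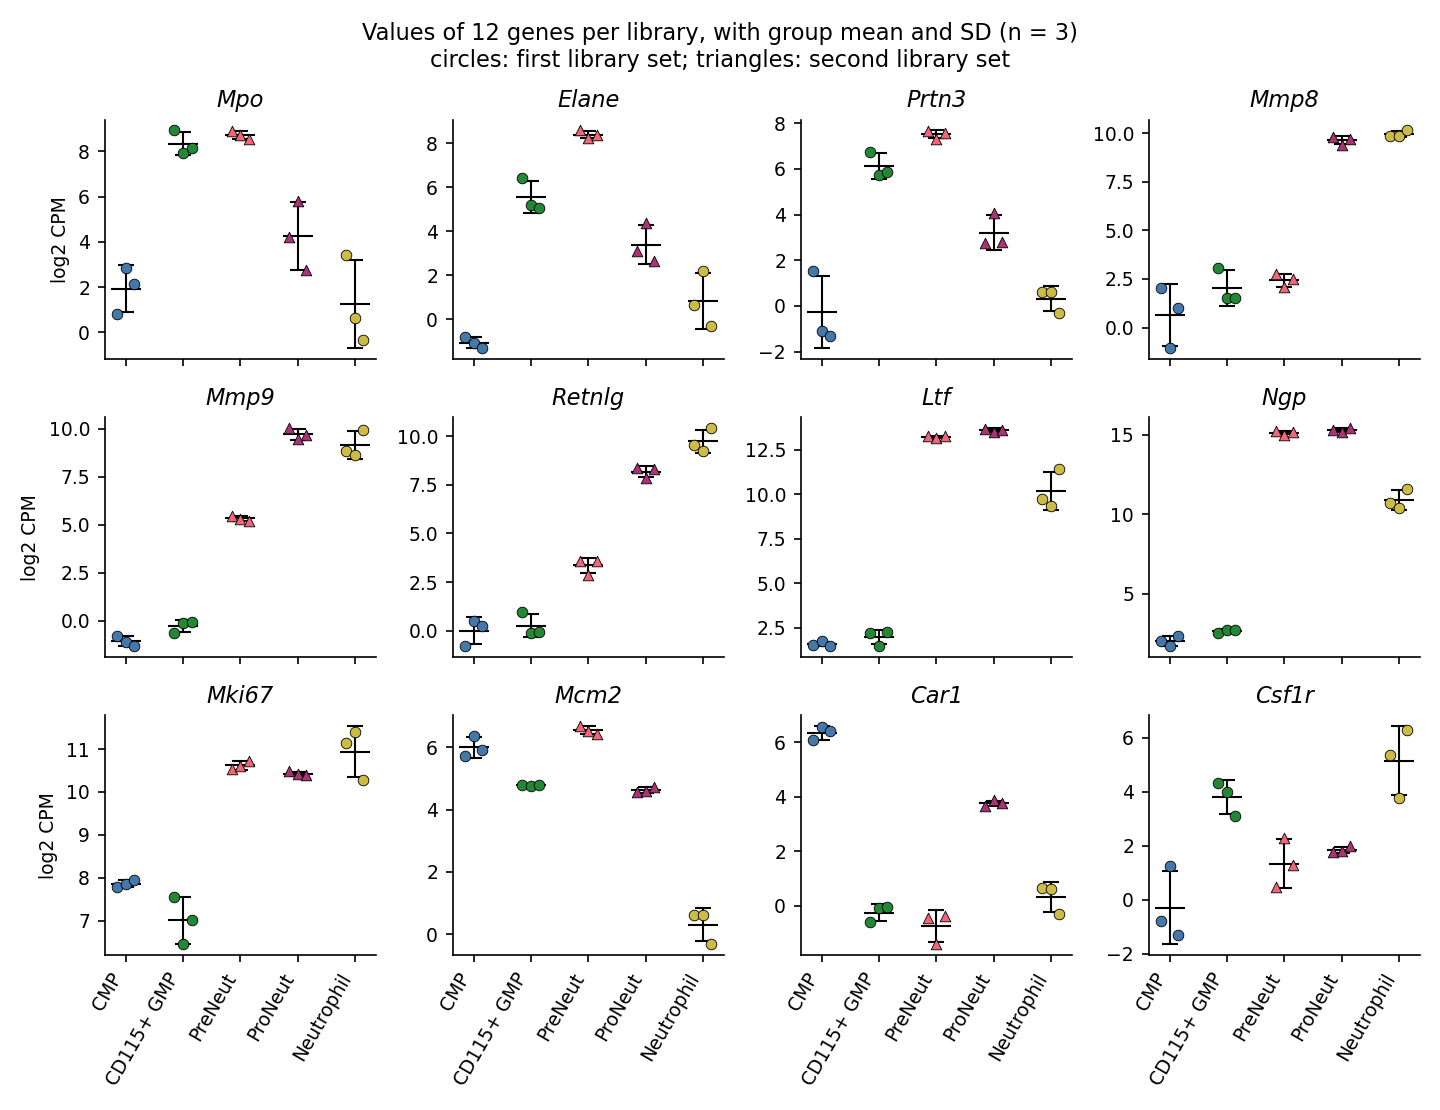
Log2 CPM of 12 genes in each of the 15 libraries, 3 points per group, with the group mean and SD (n = 3); circles are the first library set and triangles the second. Elane, Mpo and Prtn3 are lower in ProNeut than in PreNeut, and Mmp8, Mmp9 and Retnlg are higher.

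**Figure D3:**
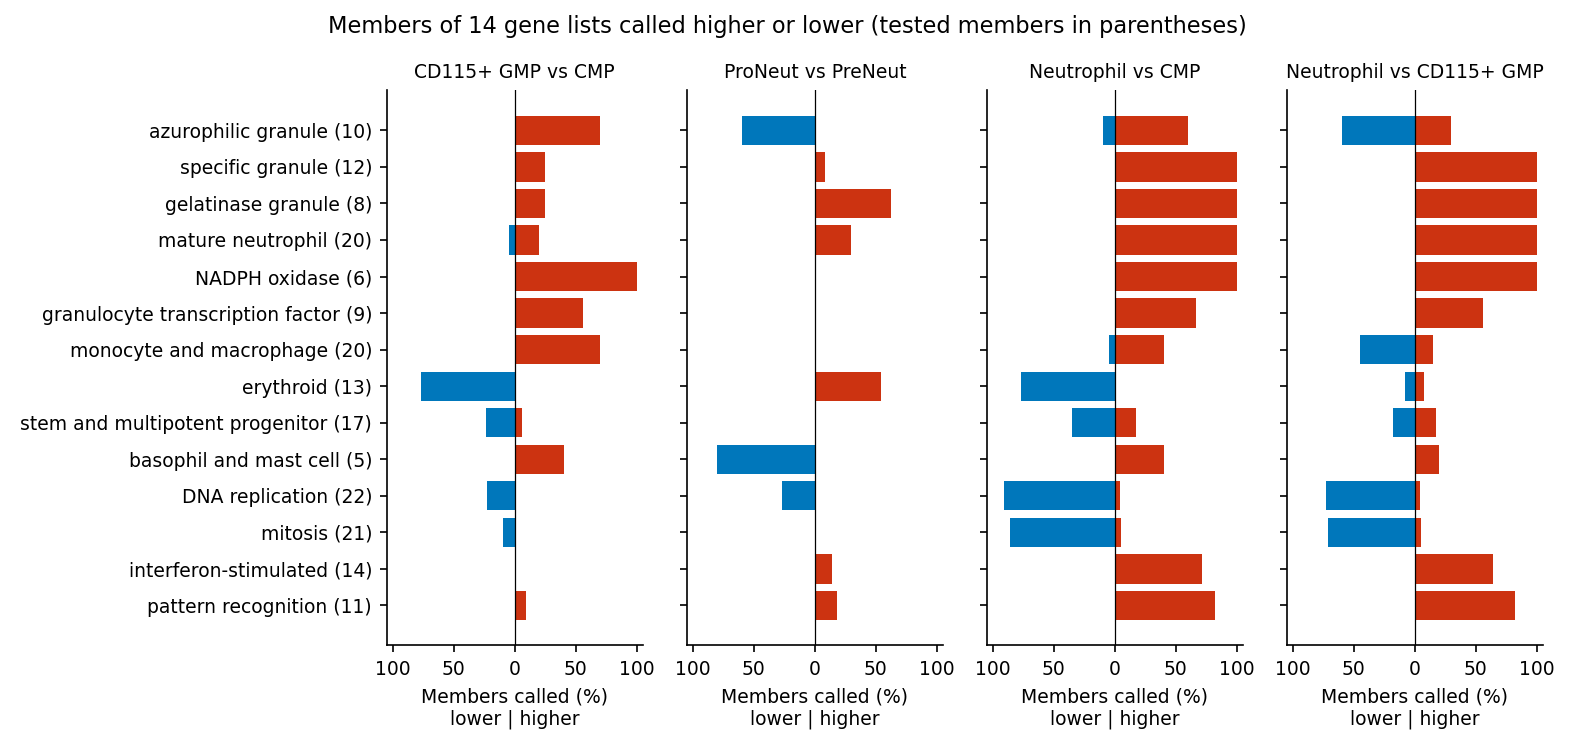
Share of tested members, in percent, of 14 gene lists called higher (to the right) or lower (to the left) in the 4 comparisons within a library set; the number of tested members follows each name. Of azurophilic granule genes, 7 of 10 are higher in CD115plusGMP than in CMP and 6 of 10 are lower in ProNeut than in PreNeut. In Neutrophil against CMP, 1 azurophilic granule gene and 1 basophil and mast cell gene called higher have 0 reads in both groups.

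Neutrophil libraries share the first set with CMP and CD115plusGMP, and these comparisons ask how mature cells differ from progenitors. Against CMP, all 12 specific granule genes, all 8 gelatinase granule genes, all 20 mature neutrophil genes and all 6 NADPH oxidase genes rose in Neutrophil (adjusted p = 0.023, 0.017, 0.014 and 0.017 with an estimated correlation). The medians were 8.49, 6.66, 6.91 and 6.49 (8.83, 7.39, 7.39 and 6.90 at the bound). DNA replication genes fell in 20 of 22 and mitosis genes in 18 of 21, with 1 member higher in each (adjusted p = 0.017 and 0.035 with an estimated correlation). The mitosis gene that rose, named after its values were seen, is the proliferation marker gene Mki67, at 10.94 ± 0.60 (SD, n = 3) in Neutrophil against 7.86 ± 0.08 (3.08 ± 0.25, SE; limma adjusted p = 5.7e-08); as for all first-set values, the strand its reads come from is open. Ribosomal protein genes fell in 45 of 80 and rose in 3 (adjusted p = 0.015 with an estimated correlation), and erythroid genes fell in 10 of 13 (adjusted p = 0.017). Pattern recognition genes rose in 9 of 11 (10 over the list alone; adjusted p = 0.023 with an estimated correlation) and interferon-stimulated genes in 10 of 14 (adjusted p = 0.073 with an estimated correlation). In limma 6212 genes passed, 3792 higher and 2420 lower. Of those higher, 228 had 0 reads in both groups, where depth and scaling alone give a difference of 1.37. Of 29 lists, 18 passed camera. The split was 3636 and 3491 with quantile normalization, 5534 and 1116 with median centring and 1923 and 4652 with plain library totals.

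Against CD115plusGMP, the same 4 lists rose in Neutrophil in full, with 12 of 12, 8 of 8, 20 of 20 and 6 of 6 genes higher (adjusted p = 0.027, 0.026, 0.0067 and 0.039 with an estimated correlation). Azurophilic granule genes fell in 6 of 10 and rose in 3 (median -3.75, -3.36 at the bound; camera adjusted p = 0.017; adjusted p = 0.11 with an estimated correlation). Monocyte and macrophage genes fell in 9 of 20 and rose in 3 (adjusted p = 0.18 with an estimated correlation), and this list did not pass without Neutrophil replicate 2 (adjusted p = 0.0657). DNA replication genes fell in 16 of 22 (adjusted p = 0.026 with an estimated correlation) and mitosis genes in 15 of 21 (adjusted p = 0.055 with an estimated correlation). In limma 4726 genes passed, 2861 higher and 1865 lower, and 19 of 29 lists passed camera. The split was 2699 and 2667 with quantile normalization, 3758 and 1024 with median centring and 1799 and 3121 with plain library totals. The libraries did not overlap for 52.9% of genes against CMP and 37.2% against CD115plusGMP. Chance gives 10% only for libraries alike in depth and scaling. The value of 0 reads was higher in every Neutrophil library than in every CMP library. The 884 tested genes with 0 reads in both of these groups are therefore non-overlapping by construction. Such values of Neutrophil and CD115plusGMP libraries overlap, so these shares cannot be set against each other.

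PreNeut against CMP asks what sets the first neutrophil-labelled subset apart from a less committed progenitor, across the 2 sets. Genes of specific granules, the second granules made, made up 6 of the 8 largest increases. Ngp, the neutrophilic granule protein gene, was at 15.13 ± 0.12 (SD, n = 3) against 2.04 ± 0.33, higher by 13.08 ± 0.23 (SE; limma adjusted p = 2.7e-16). Chil3 and the surface antigen gene Cd177 had 0 reads in CMP and were at least 4810-fold and 1540-fold higher. The lipocalin gene Lcn2 had 2 reads in CMP, a ratio of 9580 (2650 to 79100). Camp (cathelicidin) was higher by 12.49 ± 0.69 (11.75 without CMP replicate 2) and Ltf (lactoferrin) by 11.63 ± 0.36. The lysozyme gene Lyz2 was higher by 11.19 ± 0.37, and the ficolin gene Fcnb, with 0 reads in CMP, at least 1080-fold.

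All 12 specific granule genes were higher in PreNeut (median 10.73, 9.92 at the bound; camera adjusted p = 1.6e-08; adjusted p = 0.091 with an estimated correlation), as were 8 of 10 azurophilic granule genes (adjusted p = 0.091). Elane and Ms4a3 had 0 reads in CMP and were at least 353-fold and 144-fold higher; Prtn3 had a ratio of 297 (82.3 to 2450; fitted difference 7.80, and 8.71 without CMP replicate 1). All 6 NADPH oxidase genes were higher (adjusted p = 0.08 with an estimated correlation), with Cybb at 10.91 ± 0.62 (10.26 without CMP replicate 3, 11.96 without CMP replicate 2) and Ncf1 at 8.45 ± 0.38 (9.04 without CMP replicate 1). Prtn3, Ncf1 and Gfi1 overlap exons of an opposite-strand gene. Of 9 granulocyte transcription factor genes, 8 were higher (adjusted p = 0.08 with an estimated correlation). Cebpe had 57152 reads against 1, a ratio of 934 (168 to 36900), and Gfi1 0 in CMP, at least 60.6-fold higher. Of 20 mature neutrophil genes, 15 were higher and 2 lower (15 and 3 over the list alone; 1 of the 2 lower had 0 reads in both groups; adjusted p = 0.11 with an estimated correlation), with the calprotectin genes S100a8 and S100a9 at 11.01 ± 0.64 and 9.91 ± 0.41. All 13 erythroid genes were lower (median -6.43, -6.28 at the bound; adjusted p = 0.08 with an estimated correlation), among them the transcription factor genes Klf1 (-9.96 ± 1.29) and Gata1 (-8.14 ± 1.18); these were at -7.99 and -6.07 without PreNeut replicate 3 and -11.86 and -9.30 without PreNeut replicate 1, and Gata1 at -9.04 without PreNeut replicate 2. Of 21 mitosis genes, 16 were higher and 2 lower (adjusted p = 0.39 with an estimated correlation).

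The 8 largest decreases in PreNeut against CMP were Ppifos, Samd11, Slc5a2, Fam166a, Eps8l3, Tmem88, Tsix and Asb17, and each overlaps an annotated gene on the opposite strand. Samd11 was at -4.60 ± 3.12 (SD, n = 3) against 11.08 ± 0.06, Tmem88 lower at -14.85 ± 1.02 and Tsix at -14.83 ± 1.05. Leaving out a PreNeut library moved these 3 differences to between -13.90 and -16.82, -13.36 and -16.60, and -12.90 and -16.04; replicate 3 gave the smallest and replicate 1 the largest, and without replicate 2 Samd11 was at -16.30 and Tsix at -15.54. Ppifos, Eps8l3 and Asb17 had 0 reads in PreNeut and were at least 38200-fold, 22200-fold and 17600-fold lower. Fam166a and Slc5a2, with 3 and 2 reads, had ratios of 48000 (16400 to 233000) and 68200 (18900 to 563000). Their fitted differences of -15.12 and -15.21 were -13.84 and -14.01 without PreNeut replicate 3, with Fam166a at -16.48 without replicate 2 and Slc5a2 at -16.37 without replicate 1. With plain library totals the median of all genes moves by 1.26 log2 units, and these bounds and ratios shrink with it. The Y-linked genes Ddx3y and Eif2s3y had 0 reads in CMP and were at least 23.8-fold and 29.6-fold higher in PreNeut, while Xist, of the X chromosome, was lower at -9.85 ± 0.81 (-10.50 without PreNeut replicate 2) and overlaps Tsix. Of 14161 genes, 9710 passed, 5232 higher and 4478 lower (7602 and 3598 with plain library totals), and 168 of them had 0 reads in both groups. Among annotated genes 59.8% of those lower and 39.7% of those higher overlap a gene on the opposite strand. The libraries did not overlap for 79.4% of genes. Chance gives 10% only for libraries alike in depth and scaling. The 168 genes with 0 reads in both groups are non-overlapping by construction. Of 29 lists, 12 passed camera, 0 with an estimated correlation (9 at an unadjusted p under 0.05) and 23 fry.

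PreNeut against CD115plusGMP compares the neutrophil-labelled subset with the progenitor sorted on a monocyte receptor, across the 2 sets. Specific granule genes were higher in PreNeut in 11 of 12 (median 8.85, 8.63 at the bound; camera adjusted p = 1.3e-07; adjusted p = 0.28 with an estimated correlation). Ngp was higher by 12.46 ± 0.23 (SE, n = 3; limma adjusted p = 2.9e-16), Camp by 12.10 ± 0.69 (12.97 without CD115plusGMP replicate 1), Ltf by 11.24 ± 0.36 and Cd177 by 9.21 ± 0.50 (8.53 without CD115plusGMP replicate 3). Lcn2 had 2 reads in CD115plusGMP, a ratio of 5520 (1530 to 45600), and the peptidoglycan recognition gene Pglyrp1 had 0 and was at least 411-fold higher. S100a9 was higher by 10.46 ± 0.41 and S100a8 by 9.95 ± 0.64 (8.99 without CD115plusGMP replicate 2, 10.61 without CD115plusGMP replicate 1). Monocyte and macrophage genes were lower in 14 of 20 and higher in 1 (15 and 1 over the list alone; adjusted p = 0.28 with an estimated correlation). These include the transcription factor gene Zeb2 (-7.56 ± 0.27), Fn1 (-6.30 ± 0.99; -5.71 without PreNeut replicate 3) and the chemokine receptor gene Ccr2 (-6.26 ± 0.70); Zeb2 and Fn1 overlap exons of an opposite-strand gene.

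Of 8 gelatinase granule genes, 5 were higher in PreNeut (adjusted p = 0.28 with an estimated correlation). Mmp25, with 0 reads in CD115plusGMP, was at least 48.2-fold higher, and Itgam, which encodes CD11b, higher by 6.47 ± 0.43. Mitosis genes were higher in 18 of 21 and lower in 2, and DNA replication genes in 18 of 22 and 3 (adjusted p = 0.28 with an estimated correlation for each). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was higher by 5.81 ± 0.62 (5.13 without CD115plusGMP replicate 2) and overlaps an opposite-strand gene. The centromere protein gene Cenpf was higher by 4.72 ± 0.77 (3.47 without CD115plusGMP replicate 2, 5.63 without CD115plusGMP replicate 1) and the spindle motor gene Kif11 by 4.62 ± 0.36. The 8 largest decreases, Tmem88, Tsix, Samd11, Ppifos, BB031773, Slc5a2, Plcxd1 and Mmp24, each overlap an opposite-strand gene. Tmem88, Tsix and Samd11 were at -15.52 ± 1.02, -15.50 ± 1.05 and -15.50 ± 1.02 (-14.03, -13.57 and -13.73 without PreNeut replicate 3, -17.27, -16.72 and -16.65 without PreNeut replicate 1; Tsix -16.21 and Samd11 -16.13 without PreNeut replicate 2). Ppifos and BB031773 had 0 reads in PreNeut and were at least 31300-fold and 30400-fold lower. Slc5a2, Plcxd1 and Mmp24, with 2, 3 and 1 reads, had ratios of 63000 (17400 to 521000), 58300 (19900 to 283000) and 98500 (17600 to 3890000). Fitted differences of these 3 were -13.91, -13.57 and -13.93 without PreNeut replicate 3 and -16.26, -15.92 and -15.91 without replicate 1. With plain library totals the median of all genes moves by 1.82, and the bounds and ratios shrink with it. In total 10029 genes passed, 5342 higher and 4687 lower, with a split of 3194 and 5189 with median centring and 8320 and 3411 with plain library totals. Of the 10029, 261 had 0 reads in both groups. The libraries did not overlap for 80.3% of genes, where chance gives 10% only for libraries alike in depth and scaling. The 261 genes are non-overlapping by construction. Of 29 lists, 10 passed camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 22 fry.

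Neutrophil against PreNeut and against ProNeut asks how the sorted progenitor subsets differ from marrow neutrophils, again across the 2 sets. Mitosis and DNA replication genes made up 4 of the 8 largest decreases against PreNeut and 6 of 8 against ProNeut. The topoisomerase gene Top2a had 1 read in Neutrophil against 148063 in PreNeut, a ratio of 974 (175 to 38500), and against 41867 in ProNeut, a ratio of 864 (155 to 34100). Kif11 had 0 reads and was at least 127-fold lower than in PreNeut and 123-fold lower than in ProNeut. The ribonucleotide reductase genes Rrm1 and Rrm2 also had 0 and were at least 112-fold and 101-fold lower than in PreNeut, and 58.8-fold and 49.9-fold lower than in ProNeut. The condensin gene Smc2, with 0 reads, was at least 92.6-fold and 87.9-fold lower.

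Of 21 mitosis genes, 19 were lower and none higher than in PreNeut (median -5.87, -5.07 at the bound; adjusted p = 0.2 with an estimated correlation), and also 19 and none than in ProNeut (median -5.90, -4.98 at the bound; adjusted p = 0.37). DNA replication genes were lower in 19 of 22 and higher in 2 than in PreNeut (adjusted p = 0.2 with an estimated correlation), and in 18 and 3 than in ProNeut (adjusted p = 0.37). Relative to ProNeut, Ube2c, Cenpf, the spindle gene Tpx2 and the kinesin gene Cenpe had 0 reads in Neutrophil and were at least 93.8-fold, 87.1-fold, 85.6-fold and 69.8-fold lower. The histone gene H2afx had 1 read, a ratio of 298 (53.5 to 11800; fitted difference -7.02, and -7.70 without Neutrophil replicate 2). Ube2c and H2afx overlap exons of an opposite-strand gene.

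Azurophilic granule genes were lower than in PreNeut in 7 of 10 and higher in 2 (adjusted p = 0.24 with an estimated correlation). Elane had 1 read, a ratio of 426 (76.5 to 16800), Mpo 3, a ratio of 168 (57.4 to 814), and Prtn3 0, at least 79.8-fold lower; Mpo and Prtn3 overlap exons of an opposite-strand gene. The fitted difference of Mpo was -7.48, and -8.57 and -6.69 without Neutrophil replicate 1 and 3, and that of Elane -7.56, and -8.24 without Neutrophil replicate 2. Specific granule genes were lower in 10 of 12 and higher in 1 than in PreNeut (adjusted p = 0.29 with an estimated correlation). Chil3 (-6.60 ± 0.33), Ngp (-4.22 ± 0.23) and Camp (-4.02 ± 0.69) were lower and Mmp8 was higher by 7.52 ± 0.61 (SE, n = 3; limma adjusted p = 2.4e-08). Than in ProNeut they were lower in 10 of 12 (adjusted p = 0.37 with an estimated correlation), with Chil3 at -6.60 ± 0.33, Ngp at -4.37 ± 0.23 and Lcn2 at -4.37 ± 0.47 (-4.96 without Neutrophil replicate 3). Fcnb was lower than in PreNeut at -8.63 ± 0.74 (-7.78 and -9.84 without Neutrophil replicate 3 and 1), and Ly6g, a neutrophil surface marker gene, lower than in ProNeut at -4.78 ± 0.80 (-3.58 and -5.62 without Neutrophil replicate 1 and 3).

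Of 20 mature neutrophil genes, 13 were higher and 2 lower than in PreNeut (adjusted p = 0.25 with an estimated correlation). Than in ProNeut, 10 were higher and 2 lower, and the list did not pass camera (adjusted p = 0.18). The lectin receptor gene Clec4d was higher by 11.68 ± 1.31 than in PreNeut and 5.37 ± 1.31 than in ProNeut (against PreNeut 9.35, 12.58 and 13.11 without PreNeut replicate 3, 1 and 2), and the cytokine gene Il1b by 9.42 ± 0.60 and 6.66 ± 0.60. Interferon-stimulated genes were higher in 10 of 14 than in each subset (adjusted p = 0.24 and 0.37 with an estimated correlation); against ProNeut 1 of the 10 had 0 reads in both groups. In PreNeut Ifit3 and Usp18 had 3 and 2 reads, with ratios of 1110 (335 to 5820) and 836 (183 to 7760), and Oasl2 was higher by 7.58 ± 0.65; Usp18 overlaps exons of an opposite-strand gene. Fitted differences of Ifit3 (9.41) and Usp18 (8.13) were 10.72 and 8.78 without PreNeut replicate 1 and 8.13 and 6.80 without PreNeut replicate 3; Usp18 was at 8.83 without PreNeut replicate 2 and 9.15 without Neutrophil replicate 1. Against ProNeut the interferon list did not pass without ProNeut replicate 2, ProNeut replicate 3 or Neutrophil replicate 3 (adjusted p = 0.0627, 0.0676 and 0.118).

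Large increases in Neutrophil were in genes with few or no reads in the second set. The adaptor gene Abi3 had 49244 reads and was higher than in PreNeut by 15.88 ± 0.40 and than in ProNeut by 14.25 ± 0.40. Abi3, Spatc1, Tmem132a, Epha1 and Slfn5os overlap exons of an opposite-strand gene. Against PreNeut, with 0 reads there, Spatc1, Tmem132a, Epha1, D7Ertd143e and Mmp2 were at least 264000-fold, 221000-fold, 85400-fold, 55500-fold and 32000-fold higher. Prr33, with 3 reads in PreNeut, had a ratio of 338000 (116000 to 1640000; fitted difference 17.99, and 16.71 and 19.36 without PreNeut replicate 3 and 2). Against ProNeut, Slfn5os, with 0 reads, was at least 8820-fold higher, and Spatc1 and Prr33 by 15.70 ± 1.13 (14.82 and 16.40 without ProNeut replicate 2 and 3) and 14.50 ± 0.89. Tmem132a, D7Ertd143e and Epha1, with 1, 1 and 3 reads in ProNeut, had ratios of 211000 (37900 to 8340000), 53100 (9510 to 2100000) and 27200 (9310 to 132000). The fitted difference of Tmem132a was 17.34 without ProNeut replicate 1 and that of Epha1 13.61 without ProNeut replicate 3 (16.60 and 14.44 with all). These bounds and ratios hold for the deposited library sizes only: with plain library totals the median of all genes moves by -2.63 against PreNeut and -2.54 against ProNeut, and they shrink with it.

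Against PreNeut 9319 genes passed, 5023 higher and 4296 lower, and against ProNeut 8788, 4695 higher and 4093 lower. With median centring the splits were 6664 and 1504 and 6429 and 1347, and with plain library totals 3160 and 8711 and 2650 and 8695. Of the genes called, 483 and 451 had 0 reads in both groups. Among annotated genes higher in Neutrophil, 57.6% and 59.0% overlap an opposite-strand gene, against 39.8% and 39.7% of those lower. The libraries did not overlap for 71.3% and 71.0% of genes, where chance gives 10% only for libraries alike in depth and scaling. The 483 and 451 genes with 0 reads in both groups are non-overlapping by construction. Of 29 lists, 10 and 9 passed camera, 0 with an estimated correlation (5 and 3 at an unadjusted p under 0.05) and 26 fry in each. Without ProNeut replicate 3 or Neutrophil replicate 1 the glycolysis list did not pass against ProNeut (adjusted p = 0.0537 and 0.0816), nor did mitochondrially encoded genes without Neutrophil replicate 3 (0.0576); both lists had adjusted p = 0.37 with an estimated correlation.

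The remaining pairs set ProNeut against the progenitors of the first set. Against CMP, specific granule genes were higher in ProNeut in 12 of 12, gelatinase granule genes in 8 of 8, mature neutrophil genes in 19 of 20 and NADPH oxidase genes in 6 of 6 (adjusted p = 0.063, 0.056, 0.056 and 0.056 with an estimated correlation). All 13 erythroid genes were lower (adjusted p = 0.11 with an estimated correlation). Against CD115plusGMP the 4 granule and neutrophil lists were higher in 12 of 12, 8 of 8, 16 of 20 and 6 of 6 (adjusted p = 0.13 for each with an estimated correlation), and monocyte and macrophage genes were lower in 16 of 20 and higher in 2 (adjusted p = 0.22 with an estimated correlation). In limma 9520 genes passed against CMP, 5093 higher and 4427 lower (7234 and 3356 with plain library totals). Against CD115plusGMP 9703 passed, 5192 higher and 4511 lower (3289 and 5024 with median centring, 8017 and 3051 with plain library totals). Of these, 151 and 221 had 0 reads in both groups, and set and group cannot be told apart.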

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

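The tests with voom weights, plain library totals, reads thinned to equal depth, at least 10 reads in 3 libraries, no opposite-strand overlap and the own library set only were chosen after the results were seen; the others were planned. No direction was reversed for any of the 164 named gene values or 126 list results in any setting run. The genes were named mainly for large differences in these same data, and the lists had passed camera. A reversal was thus unlikely from the start, and its absence says little about other genes or lists.

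ProNeut against PreNeut was the comparison whose count moved most often. Of its 320 genes called, the count was 124 with log2(CPM + 1), 129 with log2(CPM + 5), 121 with quantile normalization, 186 with median centring and 126 with reads thinned to equal depth. It was 903 with the 2 groups alone and also with the own library set only, 1433 with array weights and 1363 with voom weights. Leaving out 1 library gave 195 to 405; the count fell by more than 1.5 times without ProNeut replicate 2 (195) or ProNeut replicate 1 (198). The cause was not tested.

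In the other comparisons, quantile normalization called 2795 genes for CD115plusGMP against CMP (1790 in the planned test). With log2(CPM + 5) the counts were 6387 for PreNeut against CMP (9710), 6482 for PreNeut against CD115plusGMP (10029), 6052 for Neutrophil against PreNeut (9319), 5712 for Neutrophil against ProNeut (8788) and 6420 for ProNeut against CD115plusGMP (9703). Adding 5 CPM narrows differences between few reads and none by construction, and in the simulated libraries it left 0 to 3 false calls in these comparisons. It also recovered fewer simulated 8-fold changes there, 69.7% to 95.5% against 86.4% to 100% without it.

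With no opposite-strand overlap fewer genes are tested by construction. The counts were then 844 (CD115plusGMP against CMP), 4690 and 4829 (PreNeut against CMP and CD115plusGMP), 153 (ProNeut against PreNeut), 4444 and 4118 (Neutrophil against PreNeut and ProNeut), 4581 and 4637 (ProNeut against CMP and CD115plusGMP), 3073 and 2216 (Neutrophil against CMP and CD115plusGMP) and 6007 for genes differing among the 5 groups (12055).

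Leaving out 1 library at a time gave 1311 to 1706 genes for CD115plusGMP against CMP, 8966 to 9145 and 9245 to 9684 for PreNeut against CMP and CD115plusGMP, 8490 to 9438 and 7669 to 8945 for Neutrophil against PreNeut and ProNeut, 8570 to 8880 and 8704 to 9334 for ProNeut against CMP and CD115plusGMP, 5291 to 6214 and 4291 to 4888 for Neutrophil against CMP and CD115plusGMP, and 11624 to 12290 genes differing among the 5 groups. The lists past the threshold were 13 to 15, 11 to 12, 10 to 11, 10 to 12, 7 to 9, 11, 9, 18 to 19 and 16 to 18 in the same order of comparisons, and 12 to 15 for ProNeut against PreNeut.

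The list tests depended on the correlation assumed between genes. With an estimated correlation, 6 of 29 lists passed for CD115plusGMP against CMP (14 with the preset one) and 10 for Neutrophil against CD115plusGMP (19). For PreNeut against CMP and CD115plusGMP, Neutrophil against PreNeut and ProNeut, and ProNeut against CMP and CD115plusGMP, 0 passed in camera then, with 9, 2, 5, 3, 8 and 6 at an unadjusted p under 0.05; fry passed 23, 22, 26, 26, 24 and 24. For Neutrophil against ProNeut, 4 lists passed with log2 CPM above 2 in 3 libraries and 5 with at least 10 reads in 3 libraries (9 in the planned test).

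No pairing of the libraries by replicate number was seen. The labels do not say how the libraries were numbered, and a weak pairing is not excluded. After group means were removed, same-numbered libraries had a median r of 0.0126 (-0.090 to 0.145; 2 of 30 pairs over 0.1) and others 0.000844 (1 of 60). With the replicate block 285 genes were called for ProNeut against PreNeut, 1680 for CD115plusGMP against CMP and 9705 for PreNeut against CMP; no count of genes or lists moved by over 1.5 times, all 126 list results and 162 of 164 gene values kept their result, and 2 lost their call.

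Of the 164 named gene values, 6 lost their call with log2(CPM + 1), 7 with log2(CPM + 5), 6 with median centring, 11 with quantile normalization, 3 with plain library totals, 9 with reads thinned to equal depth and 1 with no trend. Calls were gained by 1 with log2(CPM + 1), and by 2 each with log2(CPM + 5), array weights, voom weights, the 2 groups alone and the own library set only (of 62). Of 984 values without 1 library, 41 lost their call. None changed with no filter, robust, no fold minimum, the stricter filter (163), at least 10 reads (162) or no opposite-strand overlap (84). Of 126 list results, 86 did not pass with an estimated correlation, and 13 with plain library totals, 12 with voom weights, 12 with at least 10 reads, 11 with the stricter filter and 11 with no opposite-strand overlap were lost. The other settings lost 0 to 9 each, and leaving out 1 library lost 26 of 756.

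Scaling moved the median of all genes by less than 0.1 for ProNeut against PreNeut. Quantile normalization moved it by -0.45 and -0.48 for Neutrophil against PreNeut and ProNeut, -0.41 for Neutrophil against CMP and 0.16 for ProNeut against CD115plusGMP, and by less than 0.1 for the others across sets. Median centring moved it by -0.45 and -0.80 for PreNeut against CMP and CD115plusGMP, -0.40 and -0.75 for ProNeut against these, 1.45 and 1.40 for Neutrophil against PreNeut and ProNeut, and 0.65 for Neutrophil against CD115plusGMP; for Neutrophil against CMP it went from 0.60 to 1.60. Plain library totals moved it by 1.26, 1.82, 1.18, 1.73, -2.63 and -2.54 in the same order, and by -1.36 and -0.81 for Neutrophil against CMP and CD115plusGMP. With log2(CPM + 5) the shifts lay between -0.47 and 0.09.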

Other observations

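The test of the cell types as the whole cause of the separation of the sets was chosen after the result was seen, as were the thinning to reads on genes with a symbol and the removal of zero-read genes; the other tests below were chosen before. Immediate early and stress genes, a class of rapidly induced genes, were higher in Neutrophil than in the progenitors of the same library set. Of 10 tested, 9 were higher than in CMP (median 4.39; adjusted p = 0.035 with an estimated correlation) and 7 than in CD115plusGMP (median 3.95; adjusted p = 0.046). Adhesion and chemotaxis receptor genes were higher in 8 of 9 than in CMP (median 5.53; adjusted p = 0.031) and in 8 of 9, with 1 lower, than in CD115plusGMP (median 3.77; adjusted p = 0.046). Pattern recognition genes were higher in 9 of 11 than in CD115plusGMP (median 3.61; adjusted p = 0.041 with an estimated correlation).

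Mitochondrially encoded and ribosomal protein genes had lower values in Neutrophil. For the former this is no measure of expression by itself: ND6 took 69.1% to 93.3% of mitochondrial reads in these libraries, so the other 12 genes rest on a remainder that differs between libraries. Of 13 mitochondrially encoded genes, 8 were lower than in CMP, and the 1 called higher had 0 reads in both groups (median -2.10; adjusted p = 0.023 with an estimated correlation). Also 8 of 13 were lower than in CD115plusGMP (median -2.31; adjusted p = 0.026). Ribosomal protein genes were lower in 32 of 80 and higher in 3 than in CD115plusGMP (adjusted p = 0.026 with an estimated correlation). Oxidative phosphorylation genes of the nucleus were lower in 26 of 77 and higher in 4 than in CMP, and glycolysis genes were higher in 9 of 17 (1 with 0 reads in both groups) and lower in 2, but these lists did not pass with an estimated correlation (adjusted p = 0.15 and 0.19). Than in CD115plusGMP, oxidative phosphorylation genes had 30 read ratios above and 35 below even. ER protein folding genes were lower in 9 of 15 than in CD115plusGMP (adjusted p = 0.055 with an estimated correlation).

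For the separation of the 2 library sets, opposite-strand counting in the first set is a candidate explanation: over 2798 pairs of overlapping genes, the values of first-set libraries followed those of the partner gene in the second set more than those of the gene itself (median difference in rank correlation 0.19, 0.0696 to 0.269 over 9 libraries). Sequencing depth alone is argued against, since second-set libraries thinned to 1174210 reads kept a median r of 0.95 with unthinned ones of their group (0.912 to 0.958), against 0.192 between sets. Thinned to the 421381 reads that the first set has on genes with a symbol, they kept 0.919 (0.876 to 0.930). The median r of Neutrophil with CMP libraries exceeded that with ProNeut libraries by 0.289 (0.141 to 0.345). It argues against cell type as the whole cause only if Neutrophil cells resemble ProNeut more than CMP, which was not tested. The value is also part of the separation to be explained. What share of each difference across sets is biological stays open, as no group was sequenced in both sets.

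Sex-linked genes split with the set. Ddx3y, Eif2s3y and Uty had 0 reads in all 9 first-set libraries and Kdm5d had 1, against 5716, 7567, 1695 and 2211 reads in the second set. Of 2044 genes with 1695 to 7567 second-set reads and no opposite-strand overlap, a share of 0.00783 had 0 reads in all 9 first-set libraries, so depth or low expression rarely gives this. In the other direction, Xist had 535 reads in the first set and 43 in the second, and its antisense partner Tsix 9651 and 30. The strand of these first-set reads is open. Animals of another sex in the 2 sets may be the source of the split. The labels do not give the sex, and such a difference would add to what separates the sets.

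Erythroid genes were higher in ProNeut than in PreNeut, with a median of 3.45 over 13 genes. Low values of the deepest PreNeut library are argued against, since the median without PreNeut replicate 3 was 3.25 (0.92 to 4.81 over the genes). RNA from CMP-like cells in the ProNeut libraries could not be decided: 15 genes high in CMP and low in the second set had a median difference of 0.68 against 0.14 for all genes as low. Of the 15, 2 had 0 reads in both groups; the other 13 had a median of 0.67 and a lower quartile of -0.08, against 0.08 for low genes with reads. Erythroid cells of the marrow as a source, and a difference between the sorted cells, may each explain it and were not tested; the sort gates are not given in the labels.

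Regrouping the libraries shows how often other splits give as much. For each comparison of 3 against 3 libraries there are 10 splits, which cannot give a share under 0.05 (the smallest is 0.1). Every split but the real one mixes the groups, which moves a difference between them into the spread and lowers the count by itself. Across sets, each such split mixes the sets as well. Low counts in these splits are thus no separate support for group differences. The real split was in each case the 1 split of 10 with as many genes called: 1790 (highest other 1) for CD115plusGMP against CMP, 9710 and 10029 (0 and 0) for PreNeut against CMP and CD115plusGMP, 320 (2) for ProNeut against PreNeut, 9319 and 8788 (0 and 0) for Neutrophil against PreNeut and ProNeut, 9520 and 9703 (0 and 0) for ProNeut against CMP and CD115plusGMP, and 6212 and 4726 (0 and 9) for Neutrophil against CMP and CD115plusGMP. For genes differing among the 5 groups, 1 of 100 splits gave as many, with 12055 against 31 at most in the others. These splits were drawn over all 15 libraries without regard to the set. Mixing the sets within groups lowers the count by itself, so this test cannot tell group from set.

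For gene list tests, as many lists passed in 1 of 10 splits for CD115plusGMP against CMP (14; highest other 11), 4 and 2 for PreNeut against CMP (12; 14) and CD115plusGMP (10; 10), and 1 for ProNeut against PreNeut (14; 11). The number was 7 and 3 for Neutrophil against PreNeut (10; 12) and ProNeut (9; 12), 6 and 4 for ProNeut against CMP (11; 13) and CD115plusGMP (9; 9), and 2 and 1 for Neutrophil against CMP (18; 18) and CD115plusGMP (19; 14). In 7 of the 10 comparisons at least 1 other split thus passed as many lists under the preset correlation. In CD115plusGMP against CMP, ProNeut against PreNeut and Neutrophil against CD115plusGMP no other split did. Other splits there still passed up to 11, 11 and 14 lists, and 1 of 10 is the smallest share possible. The count of lists is therefore weak evidence in all 10 comparisons.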
